A study of Homo sapiens with 4 samples.

How the data were processed

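Gene expression was measured with Affymetrix arrays in LNCaP cells, 2 arrays after PC-3 exosomes and 2 after PBS. The values are normalized intensities, as deposited by the authors, with 1 value per probe set. The submitters' processing notes name MAS5 and RMA without their role, order or versions, and the array annotation version and genome build are not given in the sources used here. The values are on a linear scale: the lowest per array lay near 10, at 9.72 to 10.2, and the highest at 38746 to 39563. At the same rank the 4 arrays differed by at most 0.065 on the log2 scale, so no further normalization was applied. No reference genome was used, so no positions are given. The labels' description of RNA extraction speaks of brain tissue, while every sample label says LNCaP, and the groups were taken from the sample labels. The labels do not say whether the 2 arrays of a group come from separate cultures, so the spread behind each test may be technical alone. Dose, time of exposure and exosome preparation are not used here.

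The table held 49395 probe sets, of which 102 were controls. Another 44988 named a single gene, 1832 named several and 2473 named none, and the last 2 kinds were left out of the gene-level test. The probe set with the highest mean over the 4 arrays stood for each of 18132 genes, and 11734 genes had more than 1 probe set. Levels of different probe sets were not set against each other. Values were taken to log2 of the value plus 1, so a fold is a ratio of values plus 1.

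Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), PC-3 exosomes minus PBS, two-sided. P-values were adjusted with the Benjamini-Hochberg method over 18132 genes, and the threshold was an adjusted p under 0.05. The fit had 2 residual degrees of freedom and 7.0 prior ones, and the median SE of a log2 fold change was 0.078. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so each gene's p rests on the variance model. Pearson's correlation and the SD of the log2 difference were computed for each pair of arrays. The fit was tested on simulated data with 200 changed genes, 50 at each of 4 sizes. It called 10% of the genes changed by 0.25 on the log2 scale, 66% at 0.5, 100% at 1 and 100% at 2, and 4 of its 142 calls (2.82%) were unchanged genes. The simulated values were drawn from the fit's own variance model, with independent genes. They therefore do not tell how many calls in the real data are false.

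Gene lists for pathways, prostate and other cell markers and stress responses, 42 in all, were tested with limma's camera (preset correlation 0.01, trend.var), adjusted over the lists. They held 1023 different genes, of which 944 were measured. For each list the genes past the threshold over all genes tested and adjusted over the list alone were counted, and camera with an estimated correlation and fry were run as alternatives. Of the genes past the threshold 107 were in no list. The results of 1 list, counted among the 18 higher than the other genes, and of 1 gene fixed beforehand are not reported here.

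Named genes were chosen by a rule. The largest 12 rises and 12 falls were named among genes past the threshold whose arrays did not overlap between groups. In these the brighter group's mean had to reach the median of all genes' means, an intensity of 195, and LOC symbols and open reading frames were left out. From each list described, up to 4 members past the threshold with the largest change were named, or else the 2 with the smallest p. A fixed set of 10 genes was added, of which 9 were measured. The groups, the tests, the lists, this rule and the alternatives, except the centring on spike-ins, were chosen before the data were examined.

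Alternatives were quantile normalization, centring on each array's median and a pseudocount of 16. Genes at or above the median level or the 30th percentile were tested alone, and genes were summarised by the mean of their probe sets or tested as every probe set. Others were eBayes without a trend, robust eBayes, other thresholds, the replicate number as a block, and leaving out each array. The replicate numbers 1 and 2 are not explained in the labels, so the reported fit has no block. Centring each array on its 24 poly-A spike-in probe sets was added after seeing the data. With an array left out, the lone array of its group is assumed to vary like the arrays of the other group. Figures were drawn with matplotlib 3.10.9.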

Results

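The data were 4 human gene expression arrays of LNCaP, an androgen-responsive prostate cancer cell line. In 2 of them the cells had been given exosomes, small vesicles that cells release, from PC-3, a prostate cancer line that grows without androgen. The other 2 arrays were of LNCaP cells given PBS, a buffer, as the control. The median intensity per array was 111.3 and 110.8 with PC-3 exosomes and 112.4 and 112.0 with PBS, and the number of arrays limits the precision. Across 18132 genes, which are not independent replicates, Pearson's r was 0.999 between the exosome arrays and 0.998 between the PBS arrays. Between arrays of different groups r was 0.998 in each pair. The SD of the log2 difference between 2 arrays was 0.113 and 0.132 within the groups and 0.134 to 0.157 between them. The mean SD between groups was 1.18 times the mean within groups. The ratio of the 3' to the 5' signal of beta-actin, a sign of RNA integrity, was 6.82 and 5.39 with exosomes and 5.74 and 7.17 with PBS. For GAPDH that ratio was 1.35 and 1.34 with exosomes and 1.32 and 1.33 with PBS. The poly-A spike-ins, control RNAs added to a sample, averaged 6.94 and 7.02 with exosomes and 6.90 and 6.77 with PBS on the log2 scale, a difference of 0.14. It was 0.08 without PBS replicate 2 and 0.20 without PBS replicate 1. Whether the same amount of spike-in was added per amount of RNA is not known.

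The comparison of the groups asks which genes of LNCaP changed after PC-3 exosomes. HMOX1, the enzyme that degrades heme, rose 2.56-fold (log2 fold change 1.35, SE 0.076, limma adjusted p = 1.4e-04). Its mean intensity was 710 ± 72.5 (SD, n = 2) with exosomes and 277 ± 2.08 (SD, n = 2) with PBS. DHRS3, which reduces retinaldehyde, rose 2.38-fold, from 180 ± 8.55 to 431 ± 17.6 (SD, n = 2 each, adjusted p = 1.4e-04). S100P, a calcium-binding protein, rose 2.27-fold, from 3186 ± 51.9 to 7220 ± 80.0 (SD, n = 2 each, limma adjusted p = 2.9e-06). MMP7, the protease matrilysin, rose 2.02-fold, from 349 ± 3.97 to 706 ± 48.0 (SD, n = 2 each, limma adjusted p = 2.8e-04).

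The next 8 rises ran from 1.96-fold to 1.59-fold. LCN2, a carrier of iron-binding siderophores, had a log2 fold change of 0.97 (SE 0.068). BAMBI, a pseudoreceptor that dampens TGF-beta signalling, rose by 0.96 (SE 0.056), and AKR1C2, a ketosteroid reductase that inactivates dihydrotestosterone, by 0.93 (SE 0.095). SERPINA3, the protease inhibitor alpha-1-antichymotrypsin, rose by 0.92 (SE 0.079), and ATF3, a stress-induced transcription factor, by 0.85 (SE 0.087). The chemokine CXCL10 rose by 0.76 (SE 0.11), NIBAN1, a gene induced by stress, by 0.75 (SE 0.071), and the epithelial transcription factor ELF3 by 0.67 (SE 0.055). PLAAT4, singled out after its values were seen because it had the largest fitted fold change of all genes past the threshold, was dimmer than the naming rule asks. It rose 3.87-fold (log2 1.95, SE 0.089, adjusted p = 3.6e-05), from 36.1 ± 2.29 to 142 ± 6.33 (SD, n = 2 each), in 2 of its 3 probe sets. The log2 fold change of its remaining probe set was -0.03. With PBS its mean log2 value of 5.21 was below the mean of the background controls, 5.65. These controls ran from an intensity of 10.5 to 3694 on exosome replicate 1. Their mean is therefore no cutoff for a given probe set. The background of PLAAT4 itself is not known, so the size of its fold is uncertain.

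Among the genes that fell, EPHA7, an ephrin receptor, fell 1.86-fold, from 234 ± 21.4 to 125 ± 6.99 (SD, n = 2 each, log2 -0.90, SE 0.089, limma adjusted p = 0.0026). DAPK1, a death-associated kinase, fell by 0.70 on the log2 scale (SE 0.073), and ACKR3, an atypical receptor for the chemokine CXCL12, by 0.70 (SE 0.072). RIPOR2 fell by 0.65 (SE 0.056), DSEL, a dermatan sulfate epimerase-like gene, by 0.55 (SE 0.049) and RNLS, which encodes renalase, by 0.52 (SE 0.086). CDCA3, a cell cycle gene, fell by 0.42 (SE 0.065), the receptor TNFRSF19 by 0.40 (SE 0.055) and GNAI1, an inhibitory G-protein subunit, by 0.40 (SE 0.074). CWF19L2 fell by 0.39 (SE 0.063), the transcription factor MAF by 0.37 (SE 0.048) and TMPO, a protein of the nuclear lamina, by 0.36 (SE 0.068). The adjusted p of these 11 genes lay between 0.0012 and 0.0498.

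**Figure D1:**
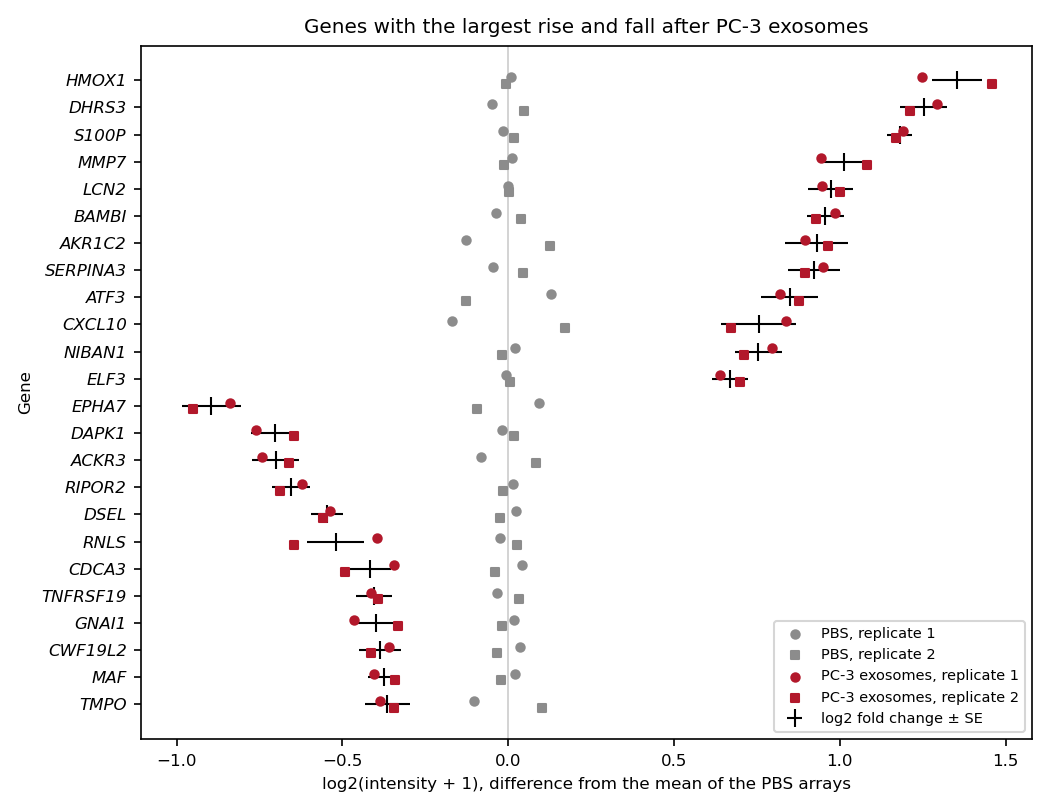
Each point is the log2(intensity + 1) of a gene on 1 array, as the difference from the mean of the PBS arrays on the x axis, for the 24 genes with the largest rise or fall on the y axis. Grey points are the 2 PBS arrays, red points the 2 exosome arrays, and the black mark and bar give the log2 fold change with its SE. HMOX1 lies at 1.35 and EPHA7 at -0.90, and in each of the 24 genes the red points lie apart from the grey ones, as the naming rule required.

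In the limma fit 127 of 18132 genes were higher and 34 lower after PC-3 exosomes at an adjusted p under 0.05. At an unadjusted p under 0.05 the counts were 1045 higher and 935 lower. The genes past the threshold had a median log2 fold change of 0.45 among those higher and -0.31 among those lower. A fold of at least 2 was reached by 6 of the genes higher and 0 of those lower. The arrays of the groups did not overlap in 39.8% of all genes, and chance gives 33.3% for 2 against 2. Leaving out an array lowered the counts to 40 higher and 7 lower without exosome replicate 1, and to 28 and 5 without exosome replicate 2. They were 40 and 7 without PBS replicate 1, and 30 and 4 without PBS replicate 2. Of the 56 named genes past the threshold, 20 were past it with each of the 4 arrays left out, and 23 in none of those 4 fits. Those 20 were HMOX1, DHRS3, S100P, MMP7, LCN2, BAMBI, AKR1C1, AKR1C2, SERPINA3, ATF3, NIBAN1, ELF3, IRF1, SLC7A11, SQSTM1, PLAAT4, EPHA7, ACKR3, RIPOR2 and DSEL. DAPK1 was lost without PBS replicate 2, and its log2 fold change stayed between -0.76 and -0.65 over the 4 fits. CXCL10 stayed past the threshold only without PBS replicate 2, RNLS only without exosome replicate 1 and TMPO only without PBS replicate 1. CDCA3, TNFRSF19, GNAI1, CWF19L2 and MAF were lost whichever array was left out, with log2 fold changes from -0.49 to -0.33. With each array centred on its poly-A spike-ins, chosen after the data were seen, the median log2 fold change of all genes was -0.15 and 60 genes were higher and 326 lower, so 15.5% of the calls were higher in place of 78.9%. That scale lowers every log2 fold change by 0.14, and 56 of the 127 and 34 of the 34 remained past the threshold. A fit with the replicate number as a block, which leaves fewer residual degrees of freedom, called 2 genes higher and 0 lower.

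Of the 42 gene lists, 18 were higher and 3 lower than the other genes by limma's camera with its preset correlation of 0.01. With a correlation estimated for each list 0 of the 42 were past the threshold, the smallest adjusted p was 0.216 and 4 lists had an unadjusted p under 0.05. That estimate rests on 2 residual degrees of freedom, so this setting had little power. A list that missed it is not shown to be unchanged. By fry, which asks whether a list's genes move one way on balance, 1 list passed.

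Genes of the ATF4 and amino acid response, which cells switch on when amino acids are short or proteins misfold, stood above the other genes by camera with its preset correlation (adjusted p = 3.7e-33), but not with an estimated one (adjusted p = 0.339 with an estimated correlation). Of 35 measured, 13 rose and 0 fell over all genes tested, and 28 rose and 0 fell adjusted over the list alone. The median log2 fold change was 0.26 and stayed above 0 against the poly-A spike-ins, at 0.12. Besides ATF3, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose by 0.66 (SE 0.090), ASNS, asparagine synthetase, by 0.58 (SE 0.075) and SLC7A11, the cystine transporter, by 0.56 (SE 0.045). PCK2 was not past the threshold without exosome replicate 1 or 2, at 0.50 to 0.82 over the 4 fits, and ASNS not without exosome replicate 2 or PBS replicate 2, at 0.48 to 0.68.

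Genes of NRF2 and oxidative stress also stood above the other genes by camera (adjusted p = 2.0e-14), but not past the threshold with an estimated correlation (adjusted p = 0.216 with an estimated correlation). Of 25 measured 8 rose and 0 fell. Adjusted over the list alone, 13 rose and 0 fell. The median log2 fold change was 0.11, and -0.03 against the poly-A spike-ins. AKR1C1, a hydroxysteroid dehydrogenase, rose 2.78-fold, from 34.9 ± 0.736 to 99.8 ± 19.2 (SD, n = 2 each, log2 1.47, SE 0.12), beside HMOX1, AKR1C2 and SLC7A11. With PBS the mean log2 value of AKR1C1, 5.17, was below the background controls' mean, 5.65. Its own background is not known, so the size of its fold is uncertain. AKR1C1 and AKR1C2 are close in sequence, and whether their probe sets share signal is not known. Steroid hormone metabolism (3 of 24 rose, 0 fell, camera adjusted p = 0.012) held AKR1C1, AKR1C2 and HSD17B4, a peroxisomal enzyme that rose by 0.26 (SE 0.039). Heme and iron handling (3 of 22 rose, 0 fell, camera adjusted p = 9.7e-04) held HMOX1, BLVRB, a biliverdin reductase, at 0.23 (SE 0.041), and FTL, the ferritin light chain, at 0.20 (SE 0.034). With an estimated correlation their adjusted p were 0.374 and 0.339, and against the poly-A spike-ins their medians were -0.10 and -0.10 in place of 0.04 and 0.04. HSD17B4, BLVRB and FTL were not past the threshold with any of the 4 arrays left out, at 0.24 to 0.29, 0.21 to 0.26 and 0.19 to 0.21. The steroid list was not past it without PBS replicate 1, with a median of 0.03.

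The type I interferon response, genes that cells switch on against viruses, had a median log2 fold change of 0.17, and 0.03 against the poly-A spike-ins. The list had a camera adjusted p of 3.1e-11, an adjusted p = 0.216 with an estimated correlation and a fry adjusted p of 0.025. Of 39 measured 4 rose and 0 fell, and adjusted over the list alone 17 rose and 0 fell. The list did not move as 1: 29 members were above 0 and 10 below, among the latter MX1 at -0.06 and RSAD2 at -0.07. PARP9 and its partner DTX3L, which act together in antiviral signalling, rose by 0.58 (SE 0.069) and 0.57 (SE 0.072). IFI35 rose by 0.49 (SE 0.075), and IFIH1, a sensor of viral RNA, by 0.45 (SE 0.080). PARP9 was past the threshold in 1 of the 4 fits with an array left out (lost without exosome replicate 2, PBS replicate 1 and PBS replicate 2) and DTX3L in 2 (lost without replicate 2 of either group). IFI35 and IFIH1 were lost in all 4, and their log2 fold changes there were 0.45 to 0.53 and 0.42 to 0.48.

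In the list of NF-kB and inflammatory genes 6 of 26 measured rose and 0 fell, 10 and 0 adjusted over the list alone. IRF1, a transcription factor of interferon signalling, rose 1.90-fold, from 76.5 ± 0.699 to 146 ± 1.77 (SD, n = 2 each, log2 0.93, SE 0.079). TNFAIP3, which limits NF-kB signalling, rose by 0.67 (SE 0.10) and CXCL8, the neutrophil chemokine, by 0.66 (SE 0.091), beside CXCL10. The median was 0.14, and 0.001 against the poly-A spike-ins. The camera adjusted p was 1.0e-06, and the adjusted p = 0.339 with an estimated correlation. TNFAIP3 and CXCL8 stayed past the threshold only without exosome replicate 1, with log2 fold changes of 0.56 to 0.77 and 0.53 to 0.79 over the 4 fits.

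Cell cycle genes were lower than the other genes by camera, with an adjusted p of 5.4e-26 for mitosis and G2/M and 2.8e-15 for DNA replication and G1/S. With an estimated correlation neither list was past the threshold (adjusted p = 0.216 and 0.339 with an estimated correlation). The mitosis and G2/M genes had a median log2 fold change of -0.20, and 36 of 36 were below 0. Of these 3 fell and 0 rose over all genes tested, and 30 fell and 0 rose adjusted over the list alone. NDC80, a kinetochore protein, fell by 0.34 (SE 0.047), CDC20, an activator of the anaphase-promoting complex, by 0.30 (SE 0.046) and HMMR by 0.28 (SE 0.038). The DNA replication and G1/S genes had a median of -0.14, with 3 of 36 that fell and 0 that rose, 16 and 0 adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, fell by 0.28 (SE 0.045), MCM4, of the replicative helicase, by 0.22 (SE 0.041) and TYMS, thymidylate synthase, by 0.20 (SE 0.037). Against the poly-A spike-ins the medians were -0.34 and -0.28. The 6 genes were lost whichever of the 4 arrays was left out, with log2 fold changes of -0.35 to -0.17, while both lists stayed past the threshold. MKI67, the proliferation marker fixed beforehand, had a log2 fold change of -0.29 (SE 0.065, adjusted p = 0.113).

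**Figure D2:**
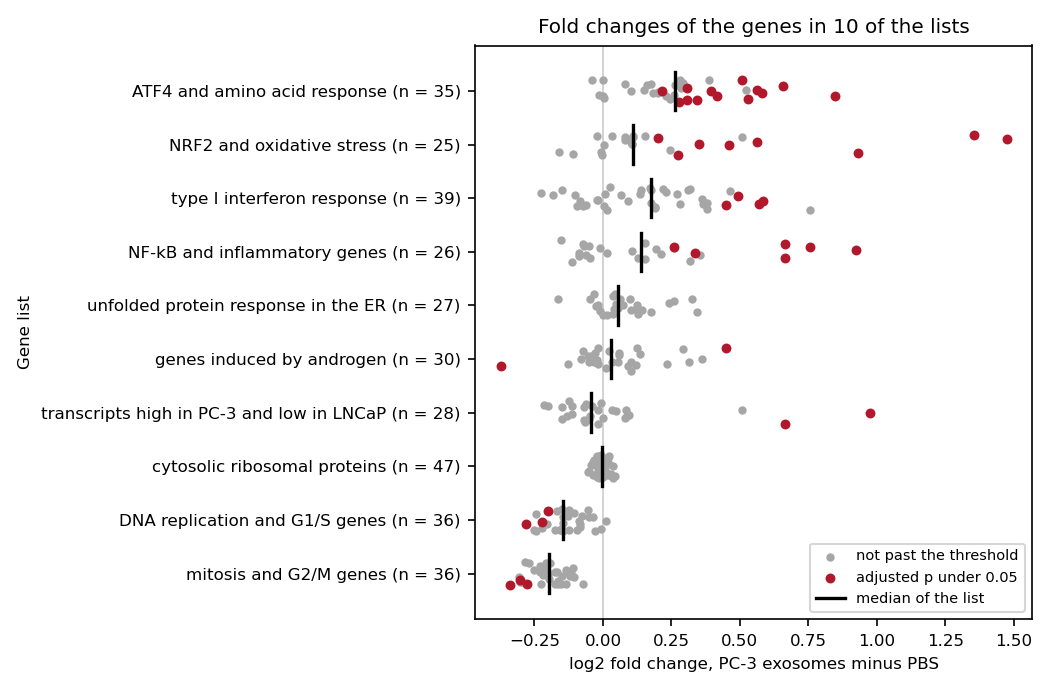
Each point is the log2 fold change of a gene, PC-3 exosomes minus PBS (x axis), in 10 of the gene lists (y axis, with the number of genes measured). Red points are genes past the adjusted threshold, grey points the other genes, and the black line is the median of the list. The ATF4 and amino acid response has a median of 0.26 and the mitosis and G2/M genes one of -0.20.

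Few genes tied to prostate identity or to PC-3 passed the test. KLK3, which encodes PSA, had a log2 fold change of -0.02 (SE 0.034, adjusted p = 0.916) at 14010 ± 50.9 with exosomes and 14186 ± 481 with PBS (SD, n = 2 each, limma). TMPRSS2, induced by androgen, had 0.14 (SE 0.036, adjusted p = 0.173). In the genes induced by androgen 1 of 30 rose and 1 fell, 3 and 1 adjusted over the list alone. HPGD, which breaks down prostaglandins, rose by 0.45 (SE 0.057) and MAF fell. That list's median was 0.03, its camera adjusted p 0.018 and the adjusted p = 0.596 with an estimated correlation. The call and the gene HPGD were lost with an array left out: the list without replicate 2 of either group, HPGD with any of the 4, at 0.44 to 0.46. In the androgen-repressed genes 1 of 12 rose and 0 fell (camera adjusted p = 0.212): TNFSF10, the death ligand TRAIL, at 0.71 (SE 0.096), past the threshold only without exosome replicate 1, at 0.61 to 0.80 over the 4 fits. Its mean log2 values, 5.66 with exosomes and 4.96 with PBS, were near and below the means of the background controls (5.65 and 5.65). These means are no cutoff for a given probe set, and the background of TNFSF10 itself is not known. In the list of luminal prostate and LNCaP identity 0 of 16 passed the limma test over all genes and 5 rose adjusted over the list alone. TRPM8 had 0.31 (adjusted p = 0.097) and MSMB 0.40 (adjusted p = 0.102). Its median was 0.07, its camera adjusted p 2.6e-04 and the adjusted p = 0.395 with an estimated correlation.

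Among transcripts listed beforehand as high in PC-3 and low in LNCaP, 2 of 28 rose and 0 fell, LCN2 and CXCL8. Adjusted over the list alone 3 rose and 0 fell, with AKR1C3 at 0.51 (SE 0.13, limma adjusted p = 0.139 over all genes). The median was -0.04, the mean 0.03 and the camera direction up (adjusted p = 0.967), so that they differ in sign. VIM, the intermediate filament of mesenchymal cells, had a log2 fold change of -0.07 (SE 0.067, adjusted p = 0.780). CD44, an adhesion receptor, had -0.01 (SE 0.082, adjusted p = 0.992) and CAV1, of caveolae, -0.02 (SE 0.089, adjusted p = 0.980). CDH1, the epithelial cadherin, had 0.10 (SE 0.040, adjusted p = 0.400), and MYC 0.12 (SE 0.048, adjusted p = 0.404). In the epithelial junctions and identity list 1 of 25 rose and 1 fell, 3 and 1 adjusted over the list alone. ELF3 rose, and DSG2, a cadherin of desmosomes, fell by 0.25 (SE 0.044), lost whichever of the 4 arrays was left out at -0.29 to -0.21. The list's median was 0.05, its camera adjusted p 5.0e-04 and the adjusted p = 0.439 with an estimated correlation. The mesenchymal genes and EMT factors had a median of -0.07 and 0 of 26 past the limma threshold (1 higher and 2 lower at an unadjusted p under 0.05), with FN1 at 0.33 (adjusted p = 0.077) and TWIST1 at -0.16 (adjusted p = 0.390). FN1, fibronectin, had 8 probe sets, all above 0 and up to 0.77, of which 6 were past the threshold when every probe set was tested. As the mean of its probe sets it rose by 0.54 (adjusted p = 0.0045), and over its alternatives the adjusted p lay between 0.0045 and 0.495. That list's camera adjusted p was 0.046, with the direction down, and the adjusted p = 0.509 with an estimated correlation.

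Further lists were higher than the remaining genes by camera. In autophagy 2 of 25 rose and 0 fell, with SQSTM1, the receptor p62, at 0.50 (SE 0.036, 5694 to 8070) and OPTN at 0.56 (SE 0.071, lost whichever of the 4 arrays was left out, at 0.50 to 0.61). The median was 0.09, the camera adjusted p 5.2e-04 and the adjusted p = 0.439 with an estimated correlation. In the unfolded protein response of the ER 0 of 27 passed over all genes and 4 rose adjusted over the list alone. DNAJB9 had 0.34 (adjusted p = 0.093) and HERPUD1 0.26 (adjusted p = 0.128), with a median of 0.05, a camera adjusted p of 5.6e-05 for the list and an adjusted p = 0.439 with an estimated correlation. TGF-beta response genes (2 of 23 rose, BAMBI and THBS1, a matrix glycoprotein at 0.45) and immediate early genes (1 of 30 rose, ATF3) had camera adjusted p of 0.0075 and 0.0092. With an estimated correlation the adjusted p was 0.370 for both. The TGF-beta median was 0.008, with 12 members above and 11 below 0, and the immediate early median 0.03. Hypoxia response genes (0 of 23, 5 higher and 0 lower at an unadjusted p under 0.05, with VEGFA at 0.24 and STC2 at 0.28) had a camera adjusted p of 0.0053, and 0.441 with an estimated correlation. Exosome formation and tetraspanins (1 of 30 rose, RAB27A, a GTPase of vesicle release, at 0.32) had 0.0092, and 0.439 with an estimated correlation. Fatty acid synthesis and storage (2 of 22 rose, ME1, malic enzyme, at 0.35 and ELOVL5, a fatty acid elongase, at 0.20) had 0.038, and 0.451 with an estimated correlation. The medians of these 3 lists were 0.06, 0.03 and 0.03. Endocytosis and lysosome (median 0.03, 0 of 28, 5 higher and 1 lower at an unadjusted p under 0.05, with CTSB at 0.14 and NPC1 at -0.18) had 0.046, and 0.509 with an estimated correlation. THBS1, RAB27A and ELOVL5 were lost whichever array was left out, at 0.35 to 0.54, 0.27 to 0.36 and 0.17 to 0.23, and ME1 was kept only without PBS replicate 2, at 0.28 to 0.42.

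Since centring on the poly-A spike-ins lowers every gene alike, by 0.14, 15 of the 18 lists higher than the other genes had a median below 0 on that scale, that is all but the ATF4, interferon and NF-kB lists. The amount of spike-in per amount of RNA is not known, so that scale is not shown to be the right one. By camera 14 of the 21 lists remained past the threshold on that scale. Those lost there included hypoxia, fatty acid synthesis, endocytosis, exosome formation, the genes induced by androgen and the mesenchymal genes. Without exosome replicate 2 the hypoxia (median 0.02), immediate early (0.02), endocytosis (0.01), mesenchymal (-0.05) and fatty acid synthesis (0.03) lists were lost. Fatty acid synthesis was also lost without exosome replicate 1 (0.03) and without PBS replicate 2 (-0.01). The mesenchymal (-0.03), exosome formation (0.01) and endocytosis (0.01) lists were lost without PBS replicate 2 too.

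Of the remaining lists by camera, matrix proteases and invasion held 1 gene of 24 that rose, MMP7 (adjusted p = 0.233), and the apoptosis regulators 1 of 23, PMAIP1, which encodes NOXA, at 0.37 (adjusted p = 0.164 for the list). PMAIP1 was lost whichever of the 4 arrays was left out, at 0.34 to 0.39. WNT/beta-catenin targets held 1 of 16 that fell, TNFRSF19 (adjusted p = 0.123). By limma 0 genes passed in the cytosolic ribosomal proteins (47 measured, median -0.003), oxidative phosphorylation subunits (41, -0.02), ribosome biogenesis and MYC targets (29, -0.02) and Polycomb and chromatin regulators (26, -0.05). The same held for fatty acid oxidation (21 measured, median 0.04), heat shock proteins (20, -0.03), cholesterol synthesis and uptake (18, 0.02), glycolysis (16, 0.01) and the metallothioneins (11, 0.03). It also held for the histones (14 measured, median -0.03, mean 0.003) and the long non-coding RNAs and snoRNA hosts (6, -0.05). The histones went both ways, with 4 higher and 3 lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 histone rose and 2 fell, and 1 glycolysis gene rose. Markers of other cells gave 0 genes past the threshold for neuron and glia (21 measured, median -0.05), neuroendocrine cells (17, -0.01), fibroblasts (14, -0.02), leukocytes (14, -0.004) and basal prostate epithelium (10, -0.03). These 16 lists held 322 genes, of which 17 were higher and 18 lower at an unadjusted p under 0.05. Their camera adjusted p lay between 0.058 and 0.992. With an array left out, some passed: fatty acid oxidation without exosome replicate 2 (median 0.05) and without PBS replicate 1 (0.07), and glycolysis without exosome replicate 1 (0.05). Polycomb and chromatin regulators passed without replicate 2 of either group (-0.05 without exosome replicate 2 and -0.07 without PBS replicate 2).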

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

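The poly-A spike-ins, control RNAs outside the genes tested, stood higher in both exosome arrays than in both PBS arrays. Their mean over 24 probe sets was 6.94 and 7.02 with exosomes and 6.90 and 6.77 with PBS on the log2 scale, a difference of 0.14, while 2 arrays separate from 2 others in 33.3% of cases by chance. The difference was 0.08 without PBS replicate 2, 0.20 without PBS replicate 1, 0.18 without exosome replicate 1 and 0.10 without exosome replicate 2. Single poly-A probe sets differed by 0.01 to 0.40. Whether the same amount of spike-in was added per amount of RNA is not known, and unequal amounts could give such a difference. The hybridisation spike-ins differed by -0.003 and the background controls by -0.004. Probe sets that name no gene or several were left out of the gene-level test, and 11 of 4305 were higher after PC-3 exosomes when every probe set was tested with limma (adjusted over 49293). The largest of these had a log2 fold change of 1.72. None was lower (0 of 4305), and at an unadjusted p under 0.05 there were 189 higher and 200 lower. Over all 49293 probe sets 108 were higher and 6 lower, so the share of higher ones was 0.256% here and 0.219% overall.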

How the results depend on the processing

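The counts of genes higher after PC-3 exosomes (127) and genes lower after PC-3 exosomes (34) depended on the settings. Quantile normalization gave 181 and 70, and kept all 127 and 34. Testing genes at or above the median level gave 213 and 84, those at or above the 30th percentile 177 and 57, and an adjusted p under 0.1 gave 203 and 69. Every probe set tested on its own gave 59 and 6, eBayes without a trend 18 and 3, and the replicate block 2 and 0. A fold of at least 2 left 6 and 0, both with an adjusted and with an unadjusted p under 0.05, and an unadjusted p with a fold of at least 1.5 left 30 and 4. Centring on the poly-A spike-ins, added after seeing the data, gave 60 and 326. Leaving out 1 array gave 28 to 40 higher, 4 to 7 lower and 16 to 21 lists. The other thresholds and filters change the counts by construction. Fewer arrays and the replicate block leave fewer residual degrees of freedom, and how much of the fall this accounts for was not tested. For the remaining settings the cause was not tested. Median centring, the pseudocount, the mean of probe sets and robust eBayes stayed within 1.5 times, at 102 to 177 and 26 to 39. The correlation of same-numbered arrays' deviations from their group means was -0.04 across genes, with only 2 such pairs. Gene lists past the threshold went from 21 to 0 with an estimated correlation and 1 by fry, and to 15 to 23 otherwise. The ratio of between-group to within-group SD was 1.36 in place of 1.18 for genes at or above the median level, and that cause was not tested.

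Over the settings 1238 of 1561 values of named genes kept their side of the threshold, 11 of them with the other sign, 289 lost the call and 34 gained it. For list medians the counts were 265 (24 with the other sign), 59 and 8 of 332. With an array left out they were 298 of 424 (4 with the other sign) and 149 of 168 (11 with the other sign). No named gene past the threshold changed sign. Values near 0 did: CD44 at 0.005 to 0.03, CAV1 at 0.003 to 0.05 and KLK3 at 0.004 and 0.02 in some settings, and against the poly-A spike-ins TMPRSS2 at -0.004, CDH1 at -0.04, MYC at -0.02, HK1 at -0.01, HSPA1B at -0.03 and RPS3 at -0.10. In named genes with several probe sets none was past the threshold in the opposite direction. Among named genes past the threshold, ATF3 (5 of 7), DHRS3 (2 of 3), MMP7 (3 of 4), NIBAN1 (2 of 3), EPHA7 (4 of 5), MAF (2 of 4), RNLS (3 of 4), TMPO (7 of 9), IRF1 (3 of 4), IFIH1 (1 of 2), MCM4 (4 of 5), DSG2 (2 of 3) and PLAAT4 (2 of 3) had probe sets on both sides of 0, with the number that share the gene's direction in brackets. Named genes not past it did so too, among them MKI67 (5 of 6), VEGFA (6 of 10) and TRPM8 (2 of 3). VIM (1 of 2), NPC1 (1 of 2) and CD44 (3 of 10) were others. The weakest probe set stood at -0.015 in DAPK1, 0.02 in DTX3L and 0.08 in PARP9 and AKR1C2. Each of these had 1 probe set past the threshold when every probe set was tested. Signal over background limits the dimmer genes: the background controls averaged 5.63 to 5.67 on the log2 scale. That mean is no cutoff for a given probe set, since the controls' intensity ran from 10.5 to 3694 on exosome replicate 1.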

Other observations

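The tests on normalization, on brightness and on MHC class I presentation were planned before their results were seen, and those on PC-3 RNA, RNA integrity, the splits, retinoic acid and IL-6 were chosen after. Genes of MHC class I antigen presentation, which loads peptides for display to T cells, were noticed among the genes that rose and form no list of the report. B2M, the light chain of MHC class I, rose by 0.29 (SE 0.048, 9783 ± 715 to 11974 ± 190, SD, n = 2 each), and TAP1, of the peptide transporter, by 0.33 (SE 0.055). TAPBP, or tapasin, rose by 0.57 (SE 0.072), and the proteasome activators PSME1 and PSME2 by 0.28 (SE 0.051) and 0.22 (SE 0.041), with limma adjusted p of 0.0097 to 0.046 for the 5 genes.

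These 5 genes may be part of a rise of the whole group, a hypothesis tested on the 13 other members. The 5 were set apart because they passed the limma threshold, so the 0 of 13 that passed it carries no weight. Of the 13, 10 were above 0, with a median log2 fold change of 0.13, PSMB9 at 0.48, ERAP1 at 0.35, HLA-E at 0.26 and HLA-B at 0.26. Centring on the poly-A spike-ins lowers every log2 fold change by 0.14, more than this median, so the median would not stay above 0. Camera gave an unadjusted p of 4.8e-05 in the direction up, 1.5e-04 adjusted over the 3 lists drawn up after the data were seen, and p = 0.089 with an estimated correlation. The HLA genes resemble each other, and signal shared between their probe sets was not tested.

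PLAAT4 and DHRS3, both known to respond to retinoic acid, were among the genes with the largest rises. If retinoic acid signalling were behind them, other targets should rise, but of 15 others 2 were above 0. PLAAT4 and DHRS3 were set apart because they passed the limma threshold, so the 0 of 15 that passed it carries no weight. Setting the risen genes apart also lowers the values of the rest as a group. Their median log2 fold change was -0.08, and STRA6 had -0.22, CRABP2 -0.23 and RARA, a retinoic acid receptor, 0.21. Camera gave p = 0.028 in the direction down, 0.042 adjusted over the 3 lists, and p = 0.143 with an estimated correlation. CYP26A1, a sensitive target, was dim in both groups (19.7 and 22.6), so a response of this kind stays open.

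SERPINA3, LCN2, CFB, STAT3, IRF1, IL6ST and CEBPB rose, and a candidate explanation is a response of the kind IL-6 gives through STAT3. CFB, of complement, rose by 0.94 (SE 0.089) and STAT3 by 0.60 (SE 0.048). Of 25 other acute phase and STAT3 genes 14 were above 0, with a median log2 fold change of 0.02. The 7 genes above were set apart because they passed the limma threshold, so the 0 of 25 that passed it carries no weight. Camera gave p = 0.061 in the direction up, and p = 0.173 with an estimated correlation, so the test decides neither way. SOCS3, an early target, had -0.14, and CEBPD 0.21 (adjusted p = 0.098).

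The genes that rose might reflect RNA of PC-3 cells carried over with the exosomes. The median log2 fold change of 28 transcripts high in PC-3 and low in LNCaP was -0.0443 (95% bootstrap interval -0.07 to 0.02), below the smallest rise among the called genes, 0.20. In the 24 of them above the mean of the background controls, which is no cutoff for a given probe set, it was -0.05 (-0.07 to -0.004). The 6 at or above the median level of all genes decide nothing alone (-0.04, -0.13 to 0.82). These data hold no PC-3 array, so the listed genes' levels in PC-3 were not checked. Nor were all of them low in LNCaP: with PBS TM4SF1 stood at 693 and VIM at 551, against a median gene intensity of 195. As far as the list holds for PC-3, the median of the 28 argues against carried RNA in the proportions of PC-3 cells. It does not argue against a few transcripts packed selectively. Of the 28, 2 rose over all genes tested and 3 adjusted over the list alone. By camera the list stood above the other genes on the spike-in scale (adjusted p = 0.029). Its median there, -0.18, was below that of all genes, -0.15. That scale lowers every log2 fold change alike, so the list's standing in fold change was as deposited, where the camera adjusted p was 0.967. The call on the spike-in scale is therefore no sign of carried RNA.

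Unequal normalization or RNA integrity could also underlie the rises. Quantile normalization kept 127 of the 127 genes, but it cannot show a wrong overall level: centred on the poly-A spike-ins, which lowers every log2 fold change by 0.14, 56 of the 127 remained. The calls ended because the median log2 fold change of the other 71 went from 0.34 to 0.20 while their median SE went from 0.054 to 0.089. The offset ran from 0.08 to 0.20 with an array left out, and the smallest rise was 0.20, so normalization stays open as a source of the smaller rises and of part of the larger ones. RNA integrity stays open too, since the 127 genes were selected for a small spread within groups, and their difference of -0.0267 in a split by the beta-actin ratio decides nothing.

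With 4 arrays there are 3 splits, too few for a share under 0.05: the real split called 161 genes, the highest other 0, and 1 of the 3 reached 161, while the others had 407 and 542 genes at an unadjusted p under 0.05. Each other split puts 1 exosome and 1 PBS array on each side, so a difference between the groups widens its residual spread. That lowers its count, and the 0 calls decide nothing.

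The cell cycle genes could be lower because of a shift that depends on brightness. Of 72 genes in either cell cycle list 71 were below 0, with a median log2 fold change of -0.17, while the lowest median of 10000 random lists matched on level was -0.04. Split by the beta-actin ratio the same genes differed by -0.022 (95% bootstrap interval -0.038 to -0.015). Both argue against brightness and against RNA integrity, as beta-actin shows it, as the whole cause. The interval describes the spread over genes that move together, not over arrays, and the split mixes the groups. The GAPDH ratio was higher in both exosome arrays (1.35 and 1.34) than in both PBS arrays (1.32 and 1.33). Integrity as GAPDH shows it was not tested and cannot be told apart from the exosomes. A slower cell cycle after PC-3 exosomes is a hypothesis that stays open, as does a difference in cell density or harvest between the cultures, about which the labels say nothing.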
